A study of Solanum lycopersicum with 24 samples.

How the data were processed

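RNA sequencing was done on tomato (Solanum lycopersicum) shoot meristems of wild-type plants (WT) and of a mutant called slful. The deposited legend writes the slful genotype as ful1/ful2/mbp10/mbp20, after 4 FRUITFULL-like MADS-box genes; the kind of mutation was not given in the sources used here. Meristems were taken at 4 stages: the vegetative meristem (VM), the transition meristem (TM), the floral meristem with the inflorescence meristem beside it (FIM), and the FIM of the first sympodial shoot (SFIM). Per the labels, each sample pooled 30 to 60 meristems, RNA was extracted with a column kit and treated with DNase, and libraries were made with a TruSeq RNA kit. The 24 libraries form 8 groups of 3 biological replicates. Strandedness, the aligner and the genome build were not given in the sources used here.

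The authors deposited 1 table of expression values for 34075 genes in RPKM (reads per kilobase of gene and M of mapped reads, M standing for mega), although the table's name speaks of raw counts. The deposited sheets of the authors' own slful versus WT comparisons, 1 per stage, give a log2 fold change, a signed fold change in other units (the negative reciprocal for genes that were lower), a p-value and a false discovery rate as a p-value. Those sheets list only genes with a false discovery rate under 0.05 and an absolute log2 fold change over 1, as tested on the values, and the test behind them was not given in the sources used here. Gene descriptions were deposited for the 435 genes on those sheets alone, of which 387 were tested here. No gene ID matched the reference table of symbols that was held, so loci carry their IDs and the deposited descriptions. Symbols of loci in the lists given by ID come from lists fixed before the data were examined and are not paired with these loci in the deposited tables. Of the 55 loci in those lists, 9 had a deposited description, which matched the list in 9 cases; the other 46 had none, and they are written as listed under a symbol. Genome coordinates were not used here.

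The reads behind the RPKM values were recovered with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, from the smallest step of each library. All 25568 genes above 0 fell on whole reads, with a largest distance of 0.0033 reads from a whole number, and 22538 of 22590 genes above 0 in at least 6 libraries gave a whole length within 0.02 bases; the tolerance for whole reads was 0.02, or 0.05 for the genes left after a first pass. The totals implied by the RPKM values run from 12.93 M reads (slful TM replicate 1) to 90.37 M (WT TM replicate 3), and reads in the listed genes from 11.51 to 81.67 M. For a gene of 1 kb, 1 read equals 0.0111 to 0.0774 RPKM and the limit that 0 reads allows (3 reads) equals 0.0332 to 0.232 RPKM, depending on the library. Folds against a group in which every library had 0 reads were taken against 3 reads per library and are lower bounds; they cover counting error only, since PCR copies were not marked. The recovered reads served for depth, for lengths and for 1 alternative test.

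The plan made before the data were examined assumed counts. Because the deposited unit is RPKM, the count tests planned were replaced by limma 3.58.1 in R 4.3.3, on log2(RPKM + 0.5), for genes with at least 0.5 RPKM in at least 3 libraries (18786 genes). The added 0.5 understates the fold of low genes, and it can make 1 fold look different between stages where the level differs. One fit held all 24 libraries with a mean per group, moderated variances with a trend on the mean (20.3 residual and prior degrees of freedom), and 2-sided tests. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no threshold on the fold. The comparisons were slful versus WT at each stage, the mean of these over the stages, the genotype by stage interaction (a joint test on 3 degrees of freedom), and WT TM versus VM, FIM versus TM and SFIM versus FIM. Gene lists fixed before the data were examined, by ID or by a word in the description, were counted over all genes tested and adjusted over the list alone. ID lists with at least 3 tested members were also tested against the other genes with camera, at a preset correlation of 0.01 and then with an estimated one, adjusted over lists and stages. Because descriptions exist only for genes the authors listed as changed, lists made by description words are not independent evidence of a direction.

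Named genes followed a rule set before the data were examined. It takes the FUL-like genes, members of the ID lists, up to 4 members per description list, and, per genotype comparison, the 12 largest changes each way among called genes with a description, all 3 libraries of a group on one side of the other 3, and a mean of at least 1 CPM in the higher group. For the averaged and the WT comparisons it takes 6 each way, and for the interaction the 8 smallest adjusted p-values with a description.

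Alternatives set before the data were examined were no filter on low values, a mean of at least 1 RPKM, median-ratio scaling, a replicate block, limma voom on the recovered reads, a fit of only the 2 groups compared, a log2 fold change over 1 as well, and leaving out each library. Where this leaves 2 libraries in a group, the shared variance still serves the test. Chosen after the data were seen were pseudocounts of 0.1 and 1, removal of each library's trend with gene length (lowess, span 0.3), one precision weight per group, a replicate block within each stage or over WT TM and WT FIM, a fit of only the 4 groups whose columns share a number format, and leaving out each slful FIM library together with the length trend. A second count tool that had been planned was not run, because the deposited unit is RPKM. Since reads could be recovered and served voom, leaving it out was a choice. Replicate numbers were taken to pair libraries where the deviations from the group means of same-numbered libraries correlated above 0.1 in all 3 pairs. This was so for slful versus WT at TM (0.23, 0.18, 0.15) and for WT FIM versus TM (0.18, 0.33, 0.19). It was so for no other comparison. The labels state no shared batch or day, so the pairing comes from the data. Correlations of similar size but opposite sign occurred for WT TM versus VM (-0.16, -0.18, -0.27). These values therefore do not establish that libraries were paired.

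The test was checked on simulated reads with the measured stage means, lengths and depths and each group's median spread, drawn independently for each gene. At each stage 100 genes were changed 2-fold and 100 were changed 4-fold, out of 18705 tested. The changed genes were drawn only from genes with a mean of at least 1 RPKM at every stage. Recovery was therefore not measured for lower genes. With 1 spread shared by all groups, 2-fold changes were recovered for 100 genes at VM, 100 at TM, 99 at FIM and 100 at SFIM. Unchanged genes made up 2.4% of calls at VM, 9.1% at TM, 44.4% at FIM and 3.8% at SFIM. With 1 precision weight per group these shares were 8.3%, 3.8%, 4% and 13.4%, and 2-fold changes were recovered for 100, 100, 93 and 100 genes. With only the 2 groups compared the shares were 2%, 2%, 0% and 3.5%, and the recovered genes 97, 100, 63 and 94. In these simulated data the shared spread kept close to its nominal error at VM and SFIM. The weights did so at TM and FIM, and the 2 groups alone did so at all 4 stages. The simulation held no trend with gene length, which the real libraries show, and no correlation between replicates of the same number. It also gave all genes of a group the same spread, which real genes need not share. It therefore cannot give the error rate in the real data. Genes described in full at TM and FIM are mostly those that also pass with weights, a choice made after the data were seen.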

Results

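The data are RPKM values of 34075 tomato genes in 24 meristem libraries, 3 from each of the 2 genotypes at each of 4 stages. Depth, as implied by the values, was 29.36 to 32.66 M reads in the VM and SFIM libraries and 12.93 to 90.37 M in the TM and FIM libraries. The VM and SFIM values were deposited with at most 10 decimals and the TM and FIM values with more, so 2 export formats are present. Genotypes at 1 stage share a format, whereas WT TM versus VM and WT SFIM versus FIM cross it and cannot be told apart from a possible batch. The first principal component held 39.7% of the variance and the second 27.5%. The median SD of log2 values between replicates was 0.068 in slful VM, 0.078 in both SFIM groups, 0.099 in WT VM and WT FIM, 0.12 in slful TM, 0.138 in WT TM and 0.217 in slful FIM. Values below are mean RPKM ± SD with n = 3 per group, and fold changes are log2 with their SE. They are taken on log2(RPKM + 0.5), which understates the change of low genes. For each gene named as changed between genotypes at a single stage, all 3 slful libraries lay on one side of the 3 WT libraries, except for cytokinin oxidase4 at TM.

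**Figure D1:**
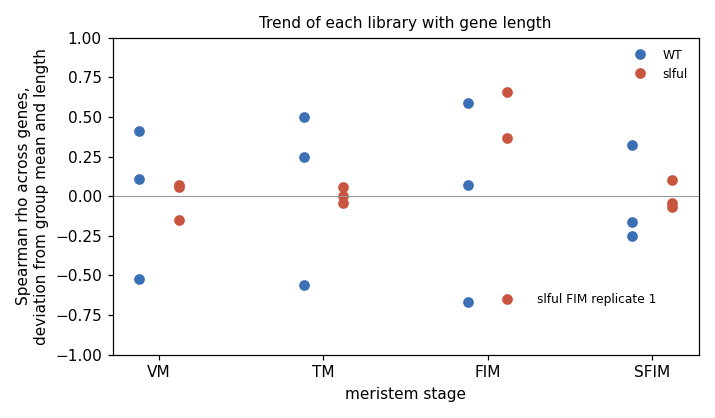
Spearman rho across genes between gene length and each library's deviation from its group mean (y axis), per stage (x axis) and genotype. slful FIM replicate 1 has rho -0.65 and slful FIM replicate 3 has 0.66; genes are not independent replicates, and deviations within a group of 3 sum to 0.

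The FUL-like genes named in the slful genotype were still transcribed in slful. FUL1 (Solyc06g069430, FRUITFULL-like MADS-box 1) ran from 10.7 to 11.8 RPKM in the slful FIM libraries against 28.1 to 34.8 in WT FIM, from 8.55 to 9.38 against 19.7 to 23.1 at SFIM, and from 8.43 to 9.76 against 13.9 to 25.0 at TM. At VM the genotypes overlapped for this gene, 1.13 to 2.13 against 1.99 to 2.46 RPKM. The locus listed as FUL2 (Solyc03g114830) was at 16.3 ± 1.39 RPKM in slful SFIM against 28.2 ± 1.31 in WT, a log2 fold change of -0.78 (SE 0.13, adjusted p = 0.00419). MBP20 (Solyc02g089210, MADS box transcription factor) went the other way, with 14.1 ± 0.267 RPKM in slful VM against 5.41 ± 0.14 in WT, a log2 fold change of 1.31 (SE 0.14, adjusted p = 1.09e-05). The locus listed as MBP10 (Solyc02g065730) passed at no stage. Its highest means were 2.12 ± 0.389 RPKM in slful TM and 1.93 ± 0.102 in WT TM. At VM it had 2 reads in 1 slful library and 0 in the other 5 libraries. Averaged over stages, FUL1 fell by 1.01 on the log2 scale (SE 0.08, adjusted p = 9.67e-08) and FUL2 fell by 0.63 (SE 0.06, adjusted p = 1.92e-06), while MBP20 rose by 0.71 (SE 0.07, adjusted p = 8.17e-07). These 3 averaged calls, FUL1 and FUL2 at SFIM, FUL1 at FIM and MBP20 at VM held under every alternative run. Of the 4 FUL-like genes, 1 rose and 0 fell at VM, 1 rose and 2 fell at TM, and 2 fell at FIM and at SFIM, the others not passing. Adjusted over the list alone, 1 rose and 1 fell at VM, 1 and 2 at TM, 1 and 3 at FIM, and 1 and 2 at SFIM. The list test gave adjusted p = 0.0324 at FIM and 0.0189 at SFIM, both downward, and 0.262 and 0.258 with an estimated correlation.

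**Figure D2:**
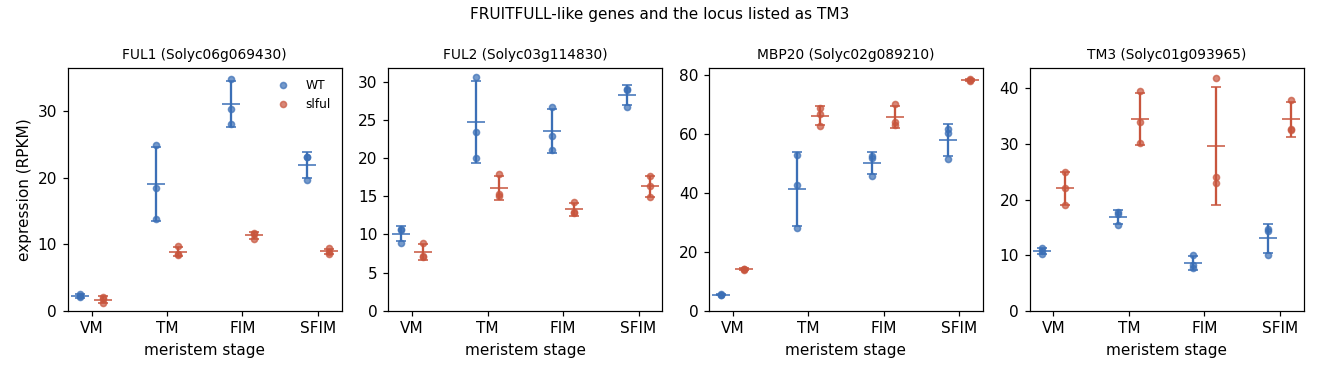
RPKM per library (y axis) of FUL1, the locus listed as FUL2, MBP20 and TM3 at each stage (x axis) in WT and slful, with mean and SD (n = 3). FUL1 lies at 11.3 ± 0.53 in slful FIM against 31.1 ± 3.42 in WT FIM, and TM3 at 34.4 ± 3.09 in slful SFIM against 13.05 ± 2.58 in WT SFIM.

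The VM comparison asked which transcripts differed in slful before the switch to flowering. A glucan endo-1,3-beta-glucosidase 12-like gene (Solyc12g040860) was at 9.54 ± 1.68 RPKM in slful against 0.152 ± 0.0214 in WT, a log2 fold change of 3.93 (SE 0.18, adjusted p = 3.46e-11). A Poly [ADP-ribose] polymerase gene (Solyc05g005290; 3.34 ± 0.366 against 0.129 ± 0.0179; 2.61, SE 0.22, adjusted p = 2.92e-07) and a 2-oxoglutarate and Fe(II)-dependent oxygenase gene (Solyc04g009860; 2.15 ± 0.301 against 0.0295 ± 0.0124; 2.32, SE 0.15, adjusted p = 6.41e-09) rose as well. Chalcone synthase 2 (Solyc05g053550), an early enzyme of flavonoid synthesis, fell from 41.8 ± 4.8 to 18.5 ± 2.48 RPKM (log2 fold change -1.16, SE 0.18, adjusted p = 0.00131). Among genes described as MADS-box, 3 of 7 rose, MBP20, Solyc03g006830 (12.7 ± 1.8 against 6.09 ± 0.266 RPKM; 1.0, SE 0.14, adjusted p = 0.000503) and TM3, 0 fell and 4 did not pass. TM3 (Solyc01g093965), a relative of the flowering activator SOC1, was at 22.0 ± 2.92 against 10.8 ± 0.544 RPKM (0.99, SE 0.18, adjusted p = 0.00736), and at 0.0679 without slful VM replicate 3. Of 7 genes described as pathogenesis-related, chitinase or WRKY, 2 chitinases rose, Solyc05g050130 (13.8 ± 1.51 against 2.58 ± 0.184; 2.21, SE 0.3, adjusted p = 0.000453) and Solyc10g055800 (3.12 ± 0.449 against 0.8885 ± 0.187; 1.38, SE 0.2, adjusted p = 0.000893), and 5 did not pass. Adjusted over the lists alone, 4 MADS-box and 3 pathogenesis-related genes rose. Both lists rest on the authors' own tables and are not independent evidence. In the SOC1/SVP-like list 1 of 4 genes rose (2 adjusted over the list alone), with a list test of adjusted p = 0.000607, which was 0.156 with an estimated correlation. limma called 84 genes at VM, 70 higher and 14 lower in slful, of which 43 changed over 2-fold. The count was 53 with a mean of at least 1 RPKM required, 313 with group weights, 154 with the VM and SFIM libraries alone, and 56 without slful VM replicate 3. Of the 23 named genes called, 14 kept their call under every alternative run, which holds for each gene named here but TM3.

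At TM, the stage of the switch to flowering, 4 genes of cytokinin breakdown were called higher in slful, but 0 of them passed with the 6 TM libraries alone. Cytokinin oxidase6 (Solyc12g008900), an enzyme that degrades cytokinin, was at 8.40 ± 3.52 RPKM against 0.907 ± 0.648 in WT, a log2 fold change of 2.68 (SE 0.39, adjusted p = 0.00122; 0.187 with the 6 libraries). Cytokinin oxidase/dehydrogenase 2 (Solyc10g017990) was at 4.75 ± 1.51 against 1.24 ± 0.901 (1.69, SE 0.32, adjusted p = 0.00935; 0.344 with the 6 libraries). All 4 genes with cytokinin in their description rose, over all genes and adjusted over the list alone, and the authors' own TM table held 3 of them. Since only genes the authors listed as changed have a description, this count is not independent evidence. Of all 387 described genes tested, 91 were called at TM. Cytokinin dehydrogenase 1 (Solyc04g016430) gave 1.32 (SE 0.24, adjusted p = 0.00781; 0.083 with group weights, 0.229 with the 6 libraries). Cytokinin oxidase4 (Solyc04g080820) gave 1.23 (SE 0.29, adjusted p = 0.0358), ending without WT TM replicate 1 (0.69, adjusted p = 0.108), slful TM replicate 1 (0.134) or slful TM replicate 2 (0.0897), and giving 0.0689 with replicate as a block within the stage and 0.5 with the 6 libraries. Over the alternatives the adjusted p ran from 0.00272 to 0.229 for the former and from 0.00222 to 0.5 for the latter. A cytokinin-related Response regulator 16,17 (Solyc06g048930) was at 36.3 ± 2.07 against 13.8 ± 8.85 RPKM (1.55, SE 0.3, adjusted p = 0.011; 0.373 with the 6 libraries).

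Further genes that were higher at TM were the glucosidase Solyc12g040860 (4.655 ± 1.96 against 0.0344 ± 0.021 RPKM; 3.20, SE 0.18, adjusted p = 9.04e-10), the oxygenase Solyc04g009860 (4.31 ± 0.378 against 0.11 ± 0.0924; 2.99, SE 0.15, adjusted p = 9.95e-11) and a glutathione S-transferase (Solyc06g075520; 1.85, SE 0.29, adjusted p = 0.00205). FUL1 fell by 1.02 (SE 0.17, adjusted p = 0.00299). A chloroplast thiamine thiazole synthase (Solyc07g064160) fell from 51.7 ± 9.55 to 22.45 ± 4.19 RPKM (-1.19, SE 0.19, adjusted p = 0.00318). A B3 domain-containing protein (Solyc07g054630) fell from 9.83 ± 1.5 to 5.03 ± 0.414 (-0.89, SE 0.13, adjusted p = 0.00155). TM3 was at 34.5 ± 4.68 against 16.9 ± 1.24 RPKM (1.0, SE 0.18, adjusted p = 0.00622). MBP20 was at 66.1 ± 3.21 against 41.2 ± 12.5 (0.72, SE 0.14, adjusted p = 0.00935; 0.47 without WT TM replicate 1). In the SOC1/SVP-like list, TM3 and the locus listed as J (Solyc11g010570; 0.38, SE 0.1, adjusted p = 0.0453) rose and 2 did not pass. Adjusted over the list alone all 4 rose. The list test gave adjusted p = 4.47e-05, and 0.115 with an estimated correlation. The tomato florigen gene, at the locus listed as SFT (Solyc03g063100), was at 12.05 ± 2.05 against 6.015 ± 3.16 RPKM (1.05, SE 0.25, adjusted p = 0.0354), 1 of 2 FT/TFL1 genes tested and 1 adjusted over the list alone. Macrocalyx (Solyc05g056620, MC in the list), a gene of sepal and inflorescence form, was at 121 ± 12.8 against 67.4 ± 25.7 RPKM (0.90, SE 0.23, adjusted p = 0.0488), 1 of 7 SEPALLATA/AP1-like genes to pass and 2 adjusted over the list alone. Several of these calls were lost when any 1 of several libraries was left out, each time with 2 libraries left in that group. J ended without WT TM replicates 1 (0.184) or 2 (0.0785) or slful TM replicates 1 (0.176) or 3 (0.0982). SFT ended without WT TM replicates 1 (0.68, adjusted p = 0.152) or 3 (0.0645) or slful TM replicates 1 (0.0625), 2 (0.0992) or 3 (0.0776), and macrocalyx without the same 5 libraries (0.218, 0.102, 0.163, 0.0888 and 0.0734). FUL2 (-0.58, SE 0.13, adjusted p = 0.0221) ended without WT TM replicate 2 (0.0817) or slful TM replicates 2 (0.0636) or 3 (0.0695). Over the alternatives the adjusted p of J ran from 0.0136 to 0.411, of SFT from 0.00288 to 0.428, of macrocalyx from 0.00926 to 0.399 and of FUL2 from 0.00625 to 0.389. With replicate as a block within the stage J gave 0.136, macrocalyx 0.0613 and FUL2 0.0554.

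limma called 339 genes at TM, 153 higher and 186 lower in slful, of which 76 changed over 2-fold (56 and 20). In the simulated data, which gave all genes of a group the same spread, 2 estimates kept their nominal error at this stage. One, with 1 weight per group, called 69 (46 higher, 23 lower), all of them among the 339, and the other, with the 6 TM libraries alone, called 4 (4 and 0). Those 69 hold cytokinin oxidase6, Cytokinin oxidase/dehydrogenase 2, the response regulator, the glucosidase, the oxygenase, the glutathione S-transferase, FUL1, TM3, MBP20, the thiamine thiazole synthase and the B3 gene. Of these genes only the glucosidase (0.0222) and the oxygenase (0.00528) also passed with the 6 TM libraries alone. Deviations of replicates of the same number correlated at TM (0.23, 0.18 and 0.15), which does not establish pairing. With replicate as a block within the stage 201 were called (117 higher, 84 lower). The balance turned to 169 higher and 135 lower with voom. The count was 592 with the length trend removed (328 higher, 264 lower), 211 without WT TM replicate 1 (158 and 53) and 111 without slful TM replicate 1 (59 and 52). It was 26 with the TM and FIM libraries alone (21 and 5). Of the 36 named genes called, 3 kept their call throughout, the glucosidase, the oxygenase and a Class I heat shock protein gene (Solyc06g076540).

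**Figure D3:**
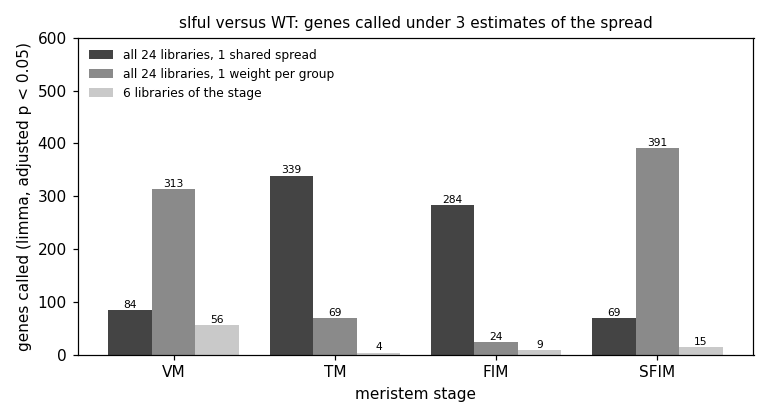
Genes called between slful and WT at each stage (x axis) by limma at an adjusted p under 0.05 (y axis, number of genes), under 3 estimates of the spread. The counts are 84, 339, 284 and 69 with 1 spread shared by the 24 libraries, 313, 69, 24 and 391 with 1 weight per group, and 56, 4, 9 and 15 with the 6 libraries of the stage alone.

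At FIM, where a flower meristem and the inflorescence meristem are both present, FUL1 fell from 31.1 ± 3.42 to 11.3 ± 0.53 RPKM, a log2 fold change of -1.41 (SE 0.17, adjusted p = 4.9e-05). TM3 rose from 8.63 ± 1.23 to 29.7 ± 10.6 RPKM (1.68, SE 0.18, adjusted p = 1.24e-05). The gene described only as NIT1 (Solyc08g078950) rose from 0.608 ± 0.305 to 4.05 ± 0.222 (2.07, SE 0.18, adjusted p = 5.73e-07). The oxygenase Solyc04g009860 was at 13.7 ± 1.42 against 1.425 ± 0.144 RPKM (2.88, SE 0.15, adjusted p = 1.99e-10). A high mobility group B protein 7 gene (Solyc06g050340) had 230 reads over the 3 slful libraries and 0 in WT, at least 40.6-fold higher (adjusted p = 3.4e-07). A Transmembrane 9 superfamily gene (Solyc10g044480; 8.01 ± 2.86 against 25.1 ± 1.27 RPKM; -1.64, SE 0.2, adjusted p = 5.52e-05), a Polyphenol oxidase (Solyc08g074682; 3.70 ± 1.18 against 10.9 ± 1.63; -1.47, SE 0.19, adjusted p = 0.000187) and the B3 gene Solyc07g054630 (4.07 ± 0.755 against 9.95 ± 0.367; -1.21, SE 0.13, adjusted p = 2.17e-05) fell. Each gene named so far in this paragraph also passed with group weights and without any 1 library. With the FIM libraries alone, FUL1, the oxygenase and the high mobility group gene kept their call. In that fit TM3 (adjusted p = 0.154), NIT1 (0.0638) and the Transmembrane 9 superfamily gene (0.14) did not pass. The Polyphenol oxidase (0.178) and the B3 gene (0.127) did not pass there either.

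In the SOC1/SVP-like list 2 of 4 genes rose at FIM, TM3 and STM3 (Solyc01g092950, MADS-box protein; 81.8 ± 31.2 against 43.2 ± 5.52 RPKM; 0.86, SE 0.16, adjusted p = 0.00821), and all 4 rose adjusted over the list alone. The list test gave adjusted p = 1.38e-05, and 0.115 with an estimated correlation. STM3 gave 0.56 without slful FIM replicate 1, and an adjusted p of 0.0572 without WT FIM replicate 1 and 0.0795 with group weights, in a range from 0.00212 to 0.492 over the alternatives. Of 7 SEPALLATA/AP1-like genes, the locus listed as RIN (Solyc05g012020), known for its part in fruit ripening, rose (0.861 ± 0.187 against 0.339 ± 0.0379 RPKM; 0.69, SE 0.16, adjusted p = 0.0298), also the only 1 adjusted over the list alone. That call ended without WT FIM replicates 1 (0.0884), 2 (0.069) or 3 (0.121) or slful FIM replicates 1 (0.123) or 2 (0.0669), in a range from 0.00562 to 0.413. Of 7 genes described as MADS-box, 3 rose, TM3, STM3 and Solyc08g080100, described as AGAMOUS (2.97 ± 0.708 against 1.16 ± 0.362; 1.07, SE 0.18, adjusted p = 0.00383), FUL1 fell and 3 did not pass. Adjusted over that list alone 4 rose and 1 fell. The AGAMOUS gene and FUL2 (-0.80, SE 0.13, adjusted p = 0.00208) did not pass with group weights (0.295 and 0.181). Over the alternatives they ran from 0.00294 to 0.298 and from 0.00191 to 0.181. Markers of other tissues moved without passing over all genes: of 7 photosynthesis genes 0 passed and 4 fell adjusted over the list alone, and of 6 trichome-type terpenoid genes 0 passed and 4 rose adjusted over the list alone. The authors' FIM table held 4 and 6 of these, so neither count is independent evidence.

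limma called 284 genes at FIM, 169 higher and 115 lower in slful, of which 82 changed over 2-fold. In the simulated data the same test at this stage made 358 calls of which 159, or 44.4%, were unchanged genes. With 1 weight per group, where that share was 4%, 24 genes were called (15 higher, 9 lower), all among the 284. The count was 103 without WT FIM replicate 3, 106 without WT FIM replicate 1, 142 without WT FIM replicate 2, 115 without slful FIM replicate 1 and 4789 without slful FIM replicate 3. That last setting turned the balance to 1175 higher and 3614 lower, and it was 848 and 1119 with the length trend also removed. The count was 172 with replicate as a block within the stage, 169 with voom, 45 with the TM and FIM libraries alone and 9 with the 6 FIM libraries alone, where the simulated share was 0% but 63 of 100 2-fold changes were recovered. FUL1, the oxygenase and the high mobility group gene were the 3 of 34 named genes called that kept their call throughout.

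At SFIM, the sympodial stage, the oxygenase Solyc04g009860 was at 14.9 ± 3.14 RPKM in slful against 1.39 ± 0.102 in WT (3.01, SE 0.15, adjusted p = 8.45e-11). NIT1 rose from 1.24 ± 0.132 to 5.77 ± 1.4 RPKM (1.83, SE 0.18, adjusted p = 6.12e-06), and TM3 from 13.05 ± 2.58 to 34.4 ± 3.09 (1.38, SE 0.18, adjusted p = 0.000263). WRKY transcription factor 28 (Solyc12g011200) rose from 0.252 ± 0.175 to 2.21 ± 0.46 (1.86, SE 0.27, adjusted p = 0.00118). A Protease inhibitor I gene (Solyc09g084460) fell from 4.54 ± 0.485 to 1.02 ± 0.272 RPKM (-1.74, SE 0.19, adjusted p = 4.01e-05). FUL1 fell from 22.0 ± 1.97 to 8.94 ± 0.418 (-1.25, SE 0.17, adjusted p = 0.000344). A BEL1-like homeodomain gene (Solyc01g007070), of a family whose proteins pair with KNOX proteins in meristems, rose from 0.0752 ± 0.0693 to 0.83 ± 0.067 RPKM (1.21, SE 0.19, adjusted p = 0.00218). The KNOX gene knox-like 1 (Solyc06g072480) was at 12 ± 2.99 against 4.89 ± 1.56 RPKM (1.23, SE 0.23, adjusted p = 0.0146). That call ended without WT SFIM replicate 1 (0.117), slful SFIM replicate 1 (0.0931) or slful SFIM replicate 2 (0.083), in a range from 0.000555 to 0.202 over the alternatives. Of 4 SOC1/SVP-like genes 1 rose, and 3 did so adjusted over the list alone. STM3 (0.0037 and 0.00741) and the locus listed as MBP24 (Solyc01g105800; 0.00211 and 0.00777) rose with group weights and with the VM and SFIM libraries alone. Both settings were chosen after the data were seen. The list test gave adjusted p = 2.03e-05, and 0.115 with an estimated correlation. Of 5 AP2-like genes 0 passed, 2 rose adjusted over the list alone, and the list test gave adjusted p = 0.0329 upward, 0.262 with an estimated correlation. APETALA2b (Solyc02g064960) had 1.32 ± 0.157 RPKM in slful against 0.292 ± 0.169 in WT (log2 fold change 1.22, SE 0.28, adjusted p = 0.0626). It passed with a replicate block (0.0333), the block within the stage (0.0316), a pseudocount of 0.1 (0.0102), group weights (0.000414) and the VM and SFIM libraries alone (0.00106). In the last 2 of these settings MBP20 (0.013 and 0.00659) and TM29 (Solyc02g089200; 0.00431 and 0.013) rose as well. Of 7 photosynthesis genes 0 passed and 3 rose adjusted over the list alone, and the authors' SFIM table held 4 of the 7, so this is not independent evidence. Of 12 inflorescence architecture genes 0 passed at any stage, with a list test of adjusted p = 0.0564 at SFIM. limma called 69 genes, 52 higher and 17 lower, of which 35 changed over 2-fold. The count was 45 without WT SFIM replicate 1, 43 without WT SFIM replicate 3, 45 without slful SFIM replicate 1 and 31 without slful SFIM replicate 3. It was 42 with replicate as a block within the stage, 391 with group weights, 176 with the VM and SFIM libraries alone and 15 with the 6 SFIM libraries alone. Of the genes named here the oxygenase, FUL1, FUL2, the protease inhibitor and the BEL1-like gene kept their call under every alternative run.

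Averaged over the stages, slful differed from WT in 663 genes, 454 higher and 209 lower, and 31 of them by over 2-fold, of which 30 were higher and FUL1 was the 1 lower. The oxygenase Solyc04g009860 (2.80, SE 0.07, adjusted p = 3.96e-16), the glucosidase Solyc12g040860 (2.37, SE 0.09, adjusted p = 4.62e-13) and the high mobility group gene Solyc06g050340 (2.09, SE 0.12, adjusted p = 4.92e-10) rose. So did Solyc12g036267 (Unknown protein; 2.94, SE 0.13, adjusted p = 2.61e-12), chosen after its values were seen. TM3 rose by 1.26 (SE 0.09, adjusted p = 9e-09), STM3 by 0.49 (SE 0.08, adjusted p = 0.000984) and the locus listed as MBP24 (Solyc01g105800) by 0.53 (SE 0.08, adjusted p = 0.000569), so 3 of 4 SOC1/SVP-like genes rose, and all 4 adjusted over the list alone. Macrocalyx rose by 0.62 (SE 0.11, adjusted p = 0.00321), 1 of 7 SEPALLATA/AP1-like genes, and 3 did adjusted over the list alone. A Methyl-CpG-binding domain gene (Solyc11g073080; -0.98, SE 0.09, adjusted p = 3.77e-07), an Exocyst complex SEC3A gene (Solyc10g073357; -0.94, SE 0.09, adjusted p = 4.52e-07) and the B3 gene Solyc07g054630 (-0.80, SE 0.07, adjusted p = 1.14e-07) fell. Of 20 named genes called, 19 kept their call under every alternative run. The locus listed as BOP2 (Solyc10g079460; -0.32, adjusted p = 0.039), 1 of 12 inflorescence architecture genes and 1 adjusted over the list alone, did not. Leaving out slful FIM replicate 3 gave 1230 genes, 663 higher and 567 lower. With group weights 519 were called, 469 of them among the main calls. With replicate as a block within each stage 514 were called, 447 of them among the main calls. The averaged test was not run on simulated data.

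Many calls recurred between stages. Of the genes higher in slful, 16 were called at all 4 stages, 13 at 3, 36 at 2 and 269 at 1. Of those lower, 1 was called at all 4, 5 at 3, 17 at 2 and 279 at 1. The 16 hold TM3, the oxygenase and its neighbour Solyc04g009850, the glucosidase, the BEL1-like gene, the heat shock gene and an AT-hook gene (Solyc12g087950), and the 1 lower at all stages is Solyc11g073080. TM and FIM shared 46 higher genes where independent lists would share 1.38, and 18 lower genes against 1.14. VM and TM shared 28 higher genes against 0.57, and FIM and SFIM 29 against 0.47. In 2 cases a gene was lower at TM and higher at SFIM, and across all genes the Spearman correlation of fold changes between stages ran from -0.01 to 0.29. Genes are not independent replicates, and the tests at all stages share 1 fit and 1 variance per gene. A gene with a low variance estimate is therefore more easily called at several stages, which the numbers for independent lists leave out. In all, 88 genes were called in the same direction at 2 or more stages, and 167 without slful FIM replicate 3. The authors' tables list 130, 124, 216 and 121 genes at VM, TM, FIM and SFIM, and 110, 103, 207 and 110 of these were tested here, each with the authors' direction. Of those tested, 54, 74, 95 and 39 were called here. In the authors' deposited table the log2 fold change at FIM is -1.41 for FUL1 and 1.86 for TM3. For genes low in WT the authors' values are larger than those here: 6.46 against 1.35 for the glucosidase and 9.69 against 3.01 for the high mobility group gene at FIM, and 6.04 against 2.32 for the oxygenase at VM. On the ratio of mean RPKM, without the added 0.5, the glucosidase gave 7.02 at FIM. Its WT FIM mean was 0.0061 RPKM, where 1 read for a gene of 1 kb equals 0.0257 to 0.0317. That ratio therefore rests on few reads and is not a measured fold. The high mobility group gene was at 0 RPKM in WT FIM, so its 3.01 is limited by the added 0.5 and no fold is measured. The oxygenase was at 0.0295 RPKM in WT VM, also below the added 0.5. The authors' lists come from the same libraries and are not independent evidence.

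The genotype effect itself differed between stages for 29 genes (adjusted p under 0.05 for the interaction), of which 8 are described in the closing section. VM and SFIM differ from TM and FIM in export format. A genotype effect that differs along that split cannot be told apart from one that depends on a possible batch. A replicate block called 19 (17 of them among the 29), and a block within each stage called 7 (5 among the 29). NIT1 had log2 fold changes of 0.50, 1.11, 2.07 and 1.83 at VM, TM, FIM and SFIM (adjusted p = 0.0217 for the difference). Of the 8 genes, only NIT1 and the transmembrane protein gene Solyc05g055680 passed with pseudocounts of 0.1 and 1 and with voom, and the other 6 lost the call in at least 1 of these. Among them is the glucosidase Solyc12g040860, at 3.93, 3.20, 1.35 and 0.97 (adjusted p = 4.43e-06), but at 5.87, 6.87, 5.89 and 4.33 with voom (adjusted p = 0.543). With a replicate block the interaction test gave an adjusted p of 0.0381 for NIT1 and 0.0617 for the transmembrane protein gene. With a block within each stage it gave 0.141 for both. For FUL1 and TM3 no difference between stages was called, although FUL1 passed at 3 stages and TM3 at 4.

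In WT all 4 FUL-like genes were higher at TM than at VM, in a comparison that crosses the export formats. FUL1 rose from 2.22 ± 0.235 to 19.1 ± 5.59 RPKM (2.81, SE 0.17, adjusted p = 4.65e-11). MBP20 rose from 5.41 ± 0.14 to 41.2 ± 12.5 (2.77, SE 0.14, adjusted p = 2.06e-12) and FUL2 from 10.1 ± 1.03 to 24.7 ± 5.38 (1.23, SE 0.13, adjusted p = 3.98e-07). MBP10 rose from 0 reads to 1.93 ± 0.102 RPKM, at least 13.8-fold (adjusted p = 1.5e-09). An inflorescence branching gene, at the locus listed as S (Solyc02g077390, COMPOUND INFLORESCENCE), rose from 0.585 ± 0.232 to 43.8 ± 6.16 RPKM (5.37, SE 0.15, adjusted p = 1.2e-16). Both FT/TFL1 genes tested rose, SFT by 3.33 (SE 0.25, adjusted p = 3.05e-09) and the locus listed as SP (Solyc06g074350) by 3.87 (SE 0.56, adjusted p = 2.89e-05). Of 7 SEPALLATA/AP1-like genes 5 rose and 2 did not pass, with macrocalyx at 67.4 ± 25.7 against 2.3 ± 1.3 RPKM (4.63, SE 0.23, adjusted p = 2.47e-12). RIN, among these 5 (0.58, adjusted p = 0.00898), lost its call without WT TM replicate 2 (0.0682, range 0.000454 to 0.091). Of 5 AP2-like genes 4 fell and 1 rose, APETALA2b falling from 51.7 ± 2.88 to 16.3 ± 7.3 RPKM (-1.75, SE 0.28, adjusted p = 7.84e-05). Of 3 CONSTANS-like genes 2 fell, and the locus listed as COL2 (Solyc02g089500) went from 1.965 ± 0.4 RPKM to 0 reads, at least 18.1-fold lower (adjusted p = 2.04e-07). In the meristem maintenance list 2 of 5 rose, the loci listed as WUS (Solyc02g083950; 1.59, SE 0.2, adjusted p = 3.95e-06) and CLV3 (Solyc11g071380; 1.08, SE 0.31, adjusted p = 0.0132). In the same list CLV1 (Solyc04g081590; -0.76, SE 0.18, adjusted p = 0.00315) fell.

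The CLV3 call at TM versus VM ended with the length trend removed (0.27, adjusted p = 0.514), without WT VM replicate 2 (0.0743) and without WT TM replicate 2 (0.0585), the lowest over the alternatives being 0.00531. Of 12 inflorescence architecture genes 3 rose and 2 fell, of 4 SOC1/SVP-like genes 1 rose and 2 fell, and of 2 organ identity genes tested Tomato AGAMOUS 1 (Solyc02g071730) rose by 2.80 (SE 0.33, adjusted p = 2.52e-06). TM3, the 1 that rose, gave 0.0509 without WT TM replicate 2, in a range from 0.00271. Adjusted over the lists alone the counts up and down were 4 and 0 for FUL-like, 2 and 0 for FT/TFL1, 6 and 0 for SEPALLATA/AP1-like, 1 and 4 for AP2-like, and 0 and 2 for CONSTANS-like genes. They were 2 and 1 for meristem maintenance, 4 and 2 for architecture, 1 and 2 for SOC1/SVP-like and 1 and 0 for organ identity genes. limma called 4710 genes, 2756 higher and 1954 lower at TM, of which 1191 changed over 2-fold, in a comparison that crosses the export formats. The split was 2439 and 2323 with median-ratio scaling and 2667 and 2821 with the length trend removed.

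From TM to FIM, within 1 export format, of 7 SEPALLATA/AP1-like genes 6 rose and 1 did not pass. The locus listed as J2 (Solyc12g038510) rose from 5.82 ± 2.68 to 37.3 ± 5.91 RPKM (2.65, SE 0.24, adjusted p = 4.52e-07). At the locus listed as EJ2 (Solyc03g114840) the rise was from 2.27 ± 1.58 to 14.5 ± 2 (2.58, SE 0.23, adjusted p = 4.22e-07). TM29 (Solyc02g089200) rose from 0.346 ± 0.159 to 5.70 ± 1.91 (2.85, SE 0.27, adjusted p = 9.05e-07). A flower identity gene, at the locus listed as AN (Solyc02g081670), rose by 2.58 (SE 0.37, adjusted p = 0.000109). TMF (Solyc09g090180), a repressor of early flowering listed under that symbol, fell from 204 ± 27.2 to 57.3 ± 6.23 RPKM (-1.82, SE 0.19, adjusted p = 3.54e-06). Of 5 AP2-like genes 4 fell and 1 rose. APETALA2b fell from 16.3 ± 7.3 to 0.4035 ± 0.102 RPKM (-4.11, SE 0.28, adjusted p = 7.85e-09). The 1 that rose, the locus listed as AP2D (Solyc11g072600; adjusted p = 0.0152), lost its call without WT TM replicate 3 (0.0709) or WT FIM replicate 1 (0.064), in a range from 0.00638 to 0.0786. The KNOX gene knox-like 1 fell from 139 ± 17.4 to 7.65 ± 1.14 RPKM (-4.10, SE 0.23, adjusted p = 4.28e-10). In the SOC1/SVP-like list 3 of 4 fell, TM3 (-0.93, SE 0.18, adjusted p = 0.00153), STM3 (-1.51, SE 0.16, adjusted p = 4.03e-06) and MBP24 (-1.55, SE 0.17, adjusted p = 4.18e-06). The 1 that rose, J (0.42, adjusted p = 0.00683), gave 0.0606 without WT TM replicate 1, in a range from 0.000774 to 0.107.

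Of the 4 FUL-like genes FUL1 rose from TM to FIM (0.72, SE 0.17, adjusted p = 0.00676; 0.0653 without WT TM replicate 1, range 0.000483 to 0.106) and MBP10 fell (-0.55, SE 0.17, adjusted p = 0.036). MBP10 lost its call without any 1 of the WT TM replicates 1, 2 and 3 (0.0838, 0.0743 and 0.0864) or WT FIM replicates 1, 2 and 3 (0.0884, 0.0857 and 0.101), in a range from 0.0165 to 0.159. Of 12 architecture genes 2 rose and 3 fell, of 5 meristem maintenance genes 3 rose, of 3 CONSTANS-like genes 1 fell, and of 2 FT/TFL1 and 2 organ identity genes 0 passed. Among these, WUS (0.82, adjusted p = 0.00923) gave 0.52 (adjusted p = 0.0802) without WT TM replicate 1 (range 0.000236 to 0.153). S (0.49, adjusted p = 0.0385) gave 0.208 and 0.0903 without WT TM replicates 1 and 3 and 0.143 and 0.13 without WT FIM replicates 1 and 2 (range 0.00826 to 0.208). Adjusted over the lists alone the counts up and down were 6 and 0 for SEPALLATA/AP1-like, 1 and 4 for AP2-like, 2 and 1 for FUL-like, and 1 and 3 for SOC1/SVP-like genes. They were 4 and 3 for architecture, 3 and 0 for meristem maintenance, 0 and 1 for CONSTANS-like, and 0 and 0 for FT/TFL1 and organ identity genes. limma called 1894 genes, 872 higher and 1022 lower at FIM, of which 461 changed over 2-fold. The split was 1022 and 980 with median-ratio scaling and 1401 and 1356 with the length trend removed. Deviations of replicates of the same number correlated here (0.18, 0.33 and 0.19), which does not establish pairing. With a replicate block over these libraries 2060 genes were called. MBP20 (0.32, adjusted p = 0.152; 0.0347 with the block) and the locus listed as BOP1 (Solyc04g040220; 0.42, adjusted p = 0.0732; 0.0462 with the block) passed only with it or in 1 to 3 other alternatives, their lowest being 0.00535 and 0.0198. The count was 985 without WT TM replicate 1 (498 and 487), 1201 without WT FIM replicate 3, 734 with the 6 libraries alone (376 and 358) and 697 with the TM and FIM libraries of both genotypes.

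**Figure D4:**
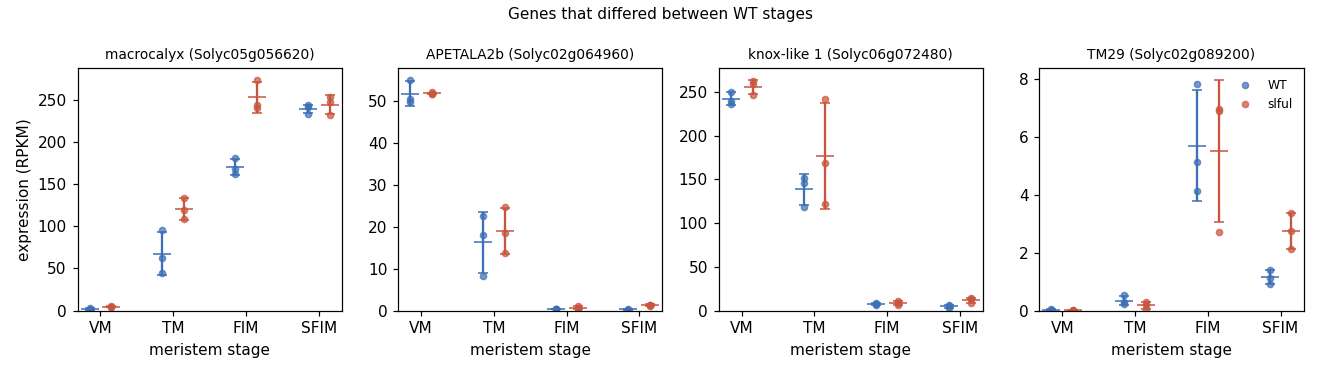
RPKM per library (y axis) of macrocalyx, APETALA2b, knox-like 1 and TM29 at each stage (x axis) in WT and slful, with mean and SD (n = 3). In WT, APETALA2b goes from 51.7 ± 2.88 at VM to 16.3 ± 7.3 at TM and 0.4035 ± 0.102 at FIM, while TM29 goes from 0.346 ± 0.159 at TM to 5.70 ± 1.91 at FIM.

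The sympodial FIM of WT was compared with the first FIM to ask how the next shoot unit differs. TCP transcription factor 7 (Solyc02g089830) rose from 0.163 ± 0.114 to 6.31 ± 1.1 RPKM (3.36, SE 0.21, adjusted p = 1.1e-10). The Protease inhibitor I gene Solyc09g084460 rose from 0.507 ± 0.24 to 4.54 ± 0.485 (2.34, SE 0.19, adjusted p = 1.7e-08). Early nodulin-93 (Solyc12g006680; 107 ± 55.2 against 6.41 ± 2.55 RPKM; 3.90, SE 0.64, adjusted p = 0.000186) and Alcohol dehydrogenase (Solyc06g059740; 187 ± 110 against 33.3 ± 3.69; 2.31, SE 0.51, adjusted p = 0.00342) were higher with a wide spread between replicates. LOB domain-containing protein 21 (Solyc03g095940) fell from 10.6 ± 2.12 to 1.59 ± 0.371 RPKM (-2.41, SE 0.23, adjusted p = 1.91e-07). A chlorophyll a-b binding protein (Solyc02g071030) fell from 22.1 ± 4.7 to 0.588 ± 0.567 (-4.52, SE 0.58, adjusted p = 9.96e-06). Of 7 SEPALLATA/AP1-like genes 3 fell, J2 (-1.17, adjusted p = 0.00144), TM29 (-1.88, adjusted p = 3.74e-05) and the locus listed as TM5 (Solyc05g015750; -1.24, adjusted p = 0.00225), RIN rose and 3 did not pass. Of 12 architecture genes 4 fell and 2 rose. The locus listed as FA (Solyc03g118160, FALSIFLORA), the tomato LEAFY gene, fell from 168 ± 7.59 to 86.9 ± 1.9 RPKM (-0.95, SE 0.14, adjusted p = 4.94e-05) and S fell by 0.90 (SE 0.15, adjusted p = 0.00024). Tomato AGAMOUS 1 rose from 1.765 ± 0.552 to 8.26 ± 2.13 RPKM (1.96, SE 0.33, adjusted p = 0.000304), 1 of 2 organ identity genes tested. COL2 went from 0 reads to 1.24 ± 0.535 RPKM, at least 7.85-fold higher (adjusted p = 1.17e-05), and with the locus listed as COL3 (Solyc02g089520; 1.01, adjusted p = 6.05e-05) 2 of 3 CONSTANS-like genes rose.

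In the same comparison 2 of 4 FUL-like genes fell, MBP10 (-0.89, SE 0.17, adjusted p = 0.000719) and FUL1 (-0.49, SE 0.17, adjusted p = 0.0479), and 2 of 4 SOC1/SVP-like genes rose, J (0.51, adjusted p = 0.000821) and TM3 (0.56, adjusted p = 0.0365). FUL1 lost its call without any 1 of the WT FIM replicates 1, 2 and 3 (0.0591, 0.0893 and 0.182) or WT SFIM replicates 1, 2 and 3 (0.169, 0.0818 and 0.0797), in a range from 0.00796 to 0.182. TM3 lost it without WT FIM replicates 1 (0.137) or 3 (0.11) or WT SFIM replicates 2 (0.151) or 3 (0.139), in a range from 0.00334 to 0.151. RIN (0.53, adjusted p = 0.0252) lost it without WT FIM replicates 1, 2 and 3 (0.057, 0.0514 and 0.0897) or WT SFIM replicates 2 and 3 (0.0841 and 0.078), in a range from 0.00241 to 0.0897. Of 5 meristem maintenance genes the locus listed as TKN1 (Solyc04g077210) rose by 0.43 (SE 0.09, adjusted p = 0.00311). CLV3 fell by 1.55 (SE 0.31, adjusted p = 0.0013; -0.56 and 0.179 with the length trend removed, the lowest alternative being 0.000201). In contrast, 0 of 5 AP2-like and 0 of 2 FT/TFL1 genes passed. Adjusted over the lists alone the counts up and down were 1 and 3 for SEPALLATA/AP1-like, 2 and 4 for architecture, 1 and 0 for organ identity, and 2 and 0 for CONSTANS-like genes. They were 0 and 2 for FUL-like, 2 and 0 for SOC1/SVP-like, 1 and 1 for meristem maintenance, 0 and 0 for AP2-like and 1 and 0 for FT/TFL1 genes. limma called 3027 genes, 1071 higher and 1956 lower at SFIM, of which 921 changed over 2-fold, in a comparison that crosses the export formats. The split was 1467 and 1507 with median-ratio scaling and 1996 and 1345 with the length trend removed. The count was 5949 with group weights and 4872 with the 6 libraries alone.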

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

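The interaction test was set before the data were examined, while the tests of scale on single genes, depth, gene length in single libraries, neighbouring genes, chromosomes, shared descriptions and stage genes at SFIM were chosen after the result was seen. The judgement on linked blocks and on an earlier state was also made more cautious after the result was seen, and the tests of depth and of length at SFIM were replaced then. A difference between stages in the slful effect marked 29 genes for a closer look. The glucosidase Solyc12g040860 had log2 fold changes of 3.93, 3.20, 1.35 and 0.97 at VM, TM, FIM and SFIM (adjusted p = 4.43e-06 for the difference). On the ratio of mean RPKM these were 5.98, 7.08, 7.02 and 4.68, without the drop from TM to FIM, and with voom the adjusted p was 0.543. The WT means were 0.0344 RPKM at TM and 0.0061 at FIM, so low that the ratios rest on few reads. The drop cannot be told apart from an effect of the added 0.5 RPKM. The Protease inhibitor I gene Solyc09g084460 had -0.05, -0.05, 0.67 and -1.74 (0.00101), and the Poly [ADP-ribose] polymerase gene Solyc05g005290 had 2.61, 1.36, 0.95 and 0.33 (0.00893). NIT1 (Solyc08g078950) had 0.50, 1.11, 2.07 and 1.83 (0.0217), and Calmodulin-like 41 (Solyc03g044900) had 1.49, 0.48, 0.17 and 0.01 (0.0225). A transmembrane protein gene (Solyc05g055680) had -0.19, 0.71, 0.90 and -0.24 (0.0394), UDP-glucuronic acid decarboxylase (Solyc05g054590) had 0.22, -0.74, -1.12 and 0.30 (0.0399), and a Quinoprotein alcohol dehydrogenase-like gene (Solyc05g055650) had 0.77, -0.79, -0.12 and 0.72 (0.0399). The transmembrane protein, decarboxylase and dehydrogenase-like genes each went one way at VM and SFIM and the other at TM and FIM. That is also the split of the export formats, so stage and a possible batch cannot be told apart for them. With a replicate block within each stage, of these 8 only the glucosidase (0.00285) and the polymerase (0.0481) passed. With a pseudocount of 0.1 the glucosidase (0.00118), NIT1 (0.0447) and the transmembrane protein gene (0.0474) passed, and with voom only NIT1 (0.0418) and the transmembrane protein gene (0.0465) did, so 0 of the 8 passed under every one of these settings.

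The count of 29 depends on single libraries. It was 13 and 11 without WT VM replicates 1 and 3, 66, 54 and 61 without WT TM replicates 1, 2 and 3, and 16, 14 and 15 without WT FIM replicates 1, 2 and 3. It was 17, 12 and 15 without WT SFIM replicates 1, 2 and 3, 14, 8 and 9 without slful VM replicates 1, 2 and 3, and 15 without slful TM replicate 3. It was 47, 19 and 79 without slful FIM replicates 1, 2 and 3, and 55, 16 and 18 without slful SFIM replicates 1, 2 and 3. Among 100 splits drawn within stages, 2 gave as many genes (the real one included), and the highest other split gave 37.

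The first pattern weighed is that slful FIM replicate 1 stands apart from its group. Counting noise from low depth does not account for it, as it would leave long and short genes alike on either side of the group mean, yet among genes of 1000 or more reads 99% of those over 4000 bases and 4.3% of those under 1000 bases lay below. Gene length bias could do so, since its deviations had a Spearman rho of -0.65 with gene length (genes are not independent replicates), and WT FIM replicate 2 (-0.67), slful FIM replicate 3 (0.66) and WT FIM replicate 1 (0.59) show the same kind of trend. The split of the FIM libraries with WT FIM replicate 2 beside slful FIM replicates 1 and 2 gave 2737 genes against 284 for the real split, so 2 of 10 splits reached the real count. No biological explanation was tested.

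The second pattern is the 31 genes with an averaged change over 2-fold, 30 of them higher in slful, and gene length bias does not account for it, as 31 of 31 kept call and direction with the length trend removed. Linked blocks around the listed FUL-like loci do not account for the 22 genes on other chromosomes, and for the 9 on the same chromosomes, FUL1 among them, they cannot be told apart from an effect of the mutations. Linked blocks of background variation elsewhere could still act, since 3 pairs lay within 3 tested genes of each other against a mean of 0.17 in 10000 random lists. Neighbouring copies of 1 gene could account for these pairs, 2 of which share a description, but not for the 25 genes in no pair. An effect of the FUL-like genes themselves remains possible.

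The third pattern is that genes falling from VM to FIM in WT were higher in slful SFIM (adjusted p = 0.000105, and 0.513 with an estimated correlation) and genes rising were lower (4.39e-06, and 0.575). Both sets passed at SFIM alone: with sets from other WT stages, falling genes were also higher at VM (0.000337, and 0.575) and FIM (4.39e-06, and 0.0669, with a median change of 0), but rising genes did not pass (0.405 at VM, 0.295 and upward at FIM). An earlier expression state in slful SFIM could give this, and tissue taken at an earlier point could as well. The data do not separate them. The sets tested at SFIM and TM come from WT FIM against WT VM, which crosses the export formats. They may therefore hold genes that differ by a possible batch rather than by stage. Gene length bias does not account for the whole of either, since with the length trend removed the mean difference between libraries was 0.086 (95% interval 0.018 to 0.154; 0.093 before) and -0.114 (-0.145 to -0.082; -0.11 before), although the median change of the falling genes went from 0.085 to 0.048. At TM the falling genes did not pass (adjusted p = 0.268, downward) and the rising genes were higher (0.000184, and 0.575). These directions are the reverse of an earlier state. The scores of the WT libraries (-2.122 to -1.192, falling less rising) enclose those of slful (-2.04 to -1.679), however. The mean difference in score was -0.173 (95% interval -1.169 to 0.824), so both an earlier and a later state there stay open.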

How the results depend on the processing

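The filters, scaling, replicate block, voom, 2-group fits and left-out libraries were chosen before the data were examined. The pseudocounts, length trend, group weights, blocks within a stage and same-format fits were chosen after. No called fold change of a named gene reversed, but the balance of higher and lower calls turned at TM, at FIM and in all 3 WT comparisons, as given in the report. Fold changes that were not called could reverse, such as Solyc09g084460 at TM, at -0.05 in the main fit and 0.78 with voom. The cause was not tested except where fewer genes or libraries make it plain. Counts below follow the order VM, TM, FIM, SFIM where 4 are given. With group weights 313, 69, 24 and 391 genes were called, and 5949 for WT SFIM versus FIM; the authors' genes called were 85, 37, 17 and 82. With a log2 fold change over 1 as well, 43, 76, 82 and 35 remained, 31 averaged, 18 for the interaction, and 1191, 461 and 921 for WT TM versus VM, FIM versus TM and SFIM versus FIM. With only the 2 groups compared, TM gave 4, FIM 9, SFIM 15, WT FIM versus TM 734 and WT SFIM versus FIM 4872. With only the 4 groups of the same format the counts were 154, 26, 45 and 176, and 697 for WT FIM versus TM. A mean of at least 1 RPKM gave 53 at VM, with 30 of the authors' genes at VM and 46 at TM. No filter gave 49 for the interaction. voom gave 169 at FIM and 13 for the interaction. Removing the length trend gave 592 at TM and 61 for the interaction, and doing so without slful FIM replicate 1, 2 or 3 gave 157, 585 and 1967 at FIM, 84, 48 and 109 for the interaction, and 1240 averaged for the last. A replicate block over all libraries gave 19 for the interaction, and a replicate block within each stage gave 201 at TM, 172 at FIM, 42 at SFIM and 7 for the interaction; the block over WT TM and FIM gave 2060 against 1894. Besides the calls named in the report, the replicate block at TM ended those of Solyc03g119590 (0.0529), Solyc02g068760 (0.0508) and Solyc12g055970 (0.0966), brought in Solyc05g050130 (0.0354) and Solyc09g015770 (0.0478), and changed no other named call.

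For the list tests, an estimated correlation gave adjusted p = 0.156, 0.115, 0.115 and 0.115 for SOC1/SVP-like genes, 0.262 at FIM and 0.258 at SFIM for FUL-like genes, and 0.262 for AP2-like genes at SFIM. FUL-like genes at FIM gave 0.062 with a mean of at least 1 RPKM and 0.0527 with a pseudocount of 0.1, and AP2-like genes at SFIM gave 0.0511 with voom and 0.0633 with a pseudocount of 1. Passing only under an alternative were SEPALLATA/AP1-like genes with voom (TM 0.0223, FIM 0.0448), architecture genes at SFIM (0.00761 with a mean of at least 1 RPKM, 0.0223 with voom) and meristem maintenance genes at TM (0.0422 with a mean of at least 1 RPKM, 0.0284 with a replicate block, 0.0178 with voom, 0.0374 with the length trend removed, 0.0203 with the block within each stage).

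Leaving out 1 library gave 56 to 82 genes at VM, 111 to 336 at TM, 103 to 4789 at FIM and 31 to 52 at SFIM, 473 to 1230 averaged and 8 to 79 for the interaction. For WT it gave 3597 to 4227 for TM versus VM, 985 to 2186 for FIM versus TM and 2060 to 2348 for SFIM versus FIM, and genes called at 2 or more stages ranged from 63 to 167. Of the named genes called, 14 of 23 at VM, 3 of 36 at TM, 3 of 34 at FIM, 6 of 22 at SFIM and 19 of 20 averaged kept their call under every alternative; in WT 35 of 40, 23 of 35 and 21 of 31 did. Depth limits low genes most in slful TM replicate 1, where 3 reads for a gene of 1 kb equal 0.232 RPKM.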

Other observations

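The tests in this part on genes read in 1 genotype and on pairs of libraries across groups were chosen after the data were seen. Some defence and wound genes were among those higher in slful. Of all 387 described genes tested, 59 were called at VM, 91 at TM, 101 at FIM and 43 at SFIM. The calls in the wound and jasmonate list do not stand out against these shares. Of 15 wound and jasmonate genes tested, 2 rose and 0 fell at TM, 2 rose and 1 fell at FIM, 1 rose and 1 fell at SFIM and 0 passed at VM; adjusted over the list alone 4 rose at TM, 7 rose and 1 fell at FIM, and 2 rose and 2 fell at SFIM. Proteinase inhibitor 1 PPI3A2 (Solyc09g089530) was at 18.6 ± 10.9 RPKM in slful TM against 3.85 ± 2.15 in WT (n = 3 each; log2 fold change 2.14, SE 0.39, adjusted p = 0.00852), and at 0.0507 without slful TM replicate 1, in a range from 0.00443 to 0.366. The jasmonate ZIM-domain protein 1 gene (Solyc12g009220), a repressor of jasmonate response, was at 7.37 ± 2.36 against 2.66 ± 1.42 RPKM at TM (1.36, SE 0.26, adjusted p = 0.00945), and at 0.0507 without slful TM replicate 1, in a range from 0.000611 to 0.373. Of 7 pathogenesis-related and WRKY genes tested, 2 rose at SFIM, WRKY transcription factor 28 and Chitinase (Solyc10g055800; 2.34 ± 0.67 against 0.75 ± 0.15; 1.16, SE 0.2, adjusted p = 0.00758), 5 did not pass, and 4 rose adjusted over the list alone. The chitinase gave 0.0509 without WT SFIM replicate 3 and 0.0786 without slful SFIM replicate 3, in a range from 0.000335 to 0.131.

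Of 5 vascular and secondary wall genes, 1 rose and 1 fell at SFIM, 3 and 1 adjusted over the list alone. Tyramine n-hydroxycinnamoyl transferase (Solyc08g068710) fell from 1.69 ± 0.417 to 0.335 ± 0.0867 RPKM (-1.38, SE 0.21, adjusted p = 0.00181). Of 2 auxin genes tested 1 rose at TM, auxin-regulated IAA3 (Solyc09g065850; 1.54 ± 0.819 against 0.376 ± 0.122 RPKM; 1.16, SE 0.23, adjusted p = 0.0111), which gave 0.0573 without slful TM replicate 1, in a range from 0.00695 to 0.344. The only cell cycle gene described, a Cyclin (Solyc11g030550), rose at FIM from 17.8 ± 2.07 to 37.1 ± 13.4 RPKM (0.99, SE 0.18, adjusted p = 0.00656; 0.0795 with group weights, range 0.00101 to 0.391). The only heat shock gene described, Solyc06g076540, rose at all 4 stages, by 2.25, 2.28, 1.90 and 1.66. No SPL, core histone or pollen gene was described, and descriptions exist only for genes the authors listed.

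Reads of 3 genes were present in every slful library (at least 5 each) and nearly absent from WT (at most 3 in all): Solyc01g056653 (874 reads against 0), the high mobility group gene Solyc06g050340 (567 against 1) and the heat shock gene Solyc06g076540 (231 against 1). In WT alone 0 genes met the same limits, and in the other splits of 100 drawn within stages the highest number was 0. Among splits for the averaged effect 1 of 100 gave as many genes (the real one), the highest other giving 279 against 663. Among the 10 splits of 6 libraries, which are too few for a share under 0.05, 1 gave as many genes (the real one) at VM, TM and SFIM, where the highest others gave 0, 98 and 7, and in WT, where they gave 3, 0 and 0. No library was a copy of another, with a chi-square per degree of freedom from 3.32 to 76.1 over the 24 pairs within groups and from 7.2 to 127 over the 252 pairs across groups.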
